A study of Mus musculus with 12 samples.

How the data were processed

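Regulatory T cells (Treg) were measured by bulk RNA sequencing. Per the labels, live CD45+ CD4+ cells that carried EGFP driven by Foxp3 and the activation marker CD69 were sorted from DEREG mice, a C57BL/6 strain with a bacterial artificial chromosome that expresses a diphtheria toxin receptor fused to EGFP under Foxp3 control. The mice had undergone ligation of the inferior vena cava, a model of deep vein thrombosis, and spleen, thrombus and vein wall were taken at day 14. Per the labels' protocols, full-length cDNA was made from 2 ng of total RNA with a SMART-Seq kit and 12 amplification cycles, and 1 ng of cDNA went into Nextera XT libraries. These libraries do not mark strand and carry no molecular identifiers, so intervals and floors given here cover counting error only.

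There were 12 libraries, 4 per tissue, numbered 1 to 4 by experiment in the labels. Nothing in the labels says whether a library came from 1 mouse or from several, so p-values measure the spread between these samples, which may be technical in part. The deposited files hold, per gene and library, counts of total exon reads, unique exon reads, intron reads and all gene reads, and RPKM values. Per the file headers, total reads include reads with more than 1 match, which make up 13.5% to 21.3% of exon reads, so near-identical paralogs (trypsins, amylases, haemoglobins) share reads here. Reads were mapped to GRCm38, per the submitters' processing notes. The aligner, the counter and their versions are not given in the sources used here. The deposited RPKM values followed from total exon reads, exon length and a read total per library, to within rounding, so the authors applied no further scaling to them.

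The files fall into 3 sets that differ in layout and gene models. Set 1 holds spleen 1 and thrombus 1. Set 2 holds spleen 2, thrombus 2 and vein wall 1, and uses NCBI rather than Ensembl gene models. Set 3 holds the other 7 libraries. The sets also differ in sex-linked reads. Set 2 libraries held both Xist and the Y-linked gene Ddx3y, set 1 Xist with almost no Ddx3y, and set 3 Ddx3y with no Xist read. Mice of both sexes in a set 2 library would give this. Effects of the set therefore cannot be told apart from those of sex or of pooled mice. Each set lists 22044 to 35817 genes with exons. Sets 1 and 3 were joined on Ensembl gene ID, with 21899 genes shared. Genes of set 2 were matched to these by name, with overlap on the same chromosome and strand required. This gave 20982 genes, of which 20977 matched by symbol and 5 by a synonym in the RefSeq gene table of GRCm38.p6. The joined genes hold 92.3% to 96.4% of exon reads. Exon length was identical over the sets for 1351 genes and within 10% for 6638. Mitochondrial genes and immunoglobulin and T cell receptor constant genes are not in the join. Gene coordinates are those of GRCm38.

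Replicate pairs of each tissue were compared by a chi-square statistic per gene with at least 40 reads over both libraries. Spleen 3 and spleen 4 gave 3.96 (median 1.19), and vein wall 3 and vein wall 4 gave 2.56 (median 0.979). The other 16 of the 18 pairs gave 96.8 to 355. The SD of the log2 ratio over genes with high counts was 0.10 and 0.09 in these pairs against 0.79 to 1.38 in the others. Each of the 2 close pairs differed by more than counting noise, which gives a mean of 1, but far less than any other pair; whether they are repeat libraries of 1 RNA is not given by the labels. Each was summed and counted as 1 sample, named spleen 3-4 and vein wall 3-4. This decision was made after the counts had been compared and before any test between tissues. It leaves 3 spleen, 4 thrombus and 3 vein wall samples, and it departs from the planned fit of 12 separate libraries, whose results are given as an alternative.

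Counts of total exon reads were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests with robust dispersion, trimmed-mean normalization (TMM), edgeR's default filter on low counts and tissue as the single factor. All 10 samples shared 1 estimate of spread. The filter kept 11722 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled by the TMM library sizes. Gene lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, two-sided, with adjustment over 99 tests (33 lists in 3 comparisons). An estimated correlation and fry were run beside it. The lists cover Treg identity, tissue and effector Treg, naive and lymphoid recirculation, tissue residence, extracellular matrix, coagulation, T cell receptor (TCR) and immediate early genes, heat shock, chemokine receptors, suppressive mediators, Th1, Th2, Th17 and follicular genes, interferon response, NF-kB signalling, proliferation, glycolysis, hypoxia, oxidative phosphorylation, heme and iron, and lipid uptake. Another 11 lists hold markers of other cell types.

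The groups, tests, gene lists, naming rule and the first group of alternatives below were fixed before the data were examined. The rule names Foxp3, Cd4, Cd69, Ptprc, Il2ra and Sparc in every tissue. It adds, per comparison and direction, the 10 called genes with the largest fold change among those with a mean of at least 20 CPM and no overlap between the groups. It also adds up to 4 called members per list, or the 2 with the smallest p where none was called. It was written for 12 libraries and applied to the 10 samples, and it gives 129 genes in 207 pairs of gene and comparison. The text prints fold changes for a part of these pairs, and that part was picked after the values were seen; the tables hold the rest. Pcsk1, Try4 and Gadd45b, and Tgif1 in thrombus, fall outside it and were named after their values were seen, as were the genes named only from the fit with the file set as covariate. A gene at 0 in a group was given a floor of 3 reads over that group.

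The test was checked on simulated counts drawn from the samples' own means, dispersions and library sizes, over 11408 tested genes. For thrombus against spleen it recovered 0 of 48 genes changed 2-fold, 11 of 45 changed 4-fold, 23 of 50 changed 8-fold and 26 of 46 changed 16-fold, with 5 false calls. For vein wall against spleen it recovered 0 of 48, 13 of 49, 20 of 50 and 28 of 49, also with 5 false calls. A simulated list of 25 genes shifted 4-fold had a camera p of 6.16e-26, or 2.23e-05 with an estimated correlation, and 2 unshifted lists, of 24 and 25 genes, had p of 0.158 and 0.985 (0.243 and 0.984 with an estimated correlation). Simulated genes were drawn independently, with no difference between file sets. Real lists in thrombus against spleen had estimated correlations such as -0.00283 (chemokine receptors), 0.138 (TCR and immediate early genes) and 0.220 (proliferation). The unshifted lists therefore do not show how the preset correlation behaves on correlated lists.

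Alternatives were other normalization, filters and tools (DESeq2 1.42.0, limma-voom, limma on RPKM with pseudocounts of 1 and 0.1), the replicate number as a block, the file set as covariate, only the 2 tissues compared, a fold threshold, and leaving out each library in turn. The fit first planned, of the 12 libraries separately, became an alternative once the near-duplicate pairs were summed. Added after the data were seen were unique exon reads, gene reads with introns, genes with exon lengths within 10%, leaving out a summed pair, and the 12 libraries with the file set as covariate. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 joined the files and ran exact permutation tests.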

Results

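The series profiled CD69+ Foxp3-EGFP+ CD4 Treg sorted from 3 sites of mice with an experimental venous thrombus at day 14: the thrombus, the vein wall around it, and the spleen as lymphoid reference. Each tissue has 4 libraries, which gave 3 spleen, 4 thrombus and 3 vein wall samples once 2 near-duplicate pairs were summed. Total exon reads were 12978484, 20283454, 55386086 and 21775744 for spleen 1 to 4, 14248733, 22038420, 9719151 and 10852343 for thrombus 1 to 4, and 18574329, 20981459, 24042703 and 20121917 for vein wall 1 to 4. Between 10309 and 11471 genes had at least 10 reads per library. A count of 0 allows 0.0563 to 0.323 CPM, depending on the library. The first principal component of log2 CPM held 23.4% of the variance and followed the set of files (r2 = 0.902) rather than tissue (r2 = 0.0289). The second, with 16%, had an r2 of 0.670 with set and 0.573 with tissue.

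**Figure D1:**
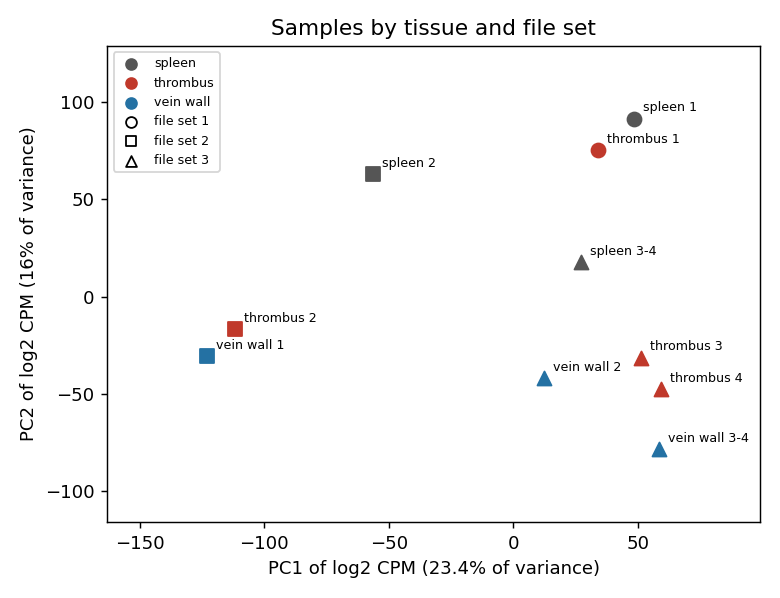
Principal components of log2 CPM over tested genes for the 10 samples, 1 point per sample, coloured by tissue and shaped by set of files. PC1 (23.4% of variance) separates the 3 samples of set 2 from the others, and PC2 (16%) places every spleen sample above every thrombus and vein wall sample of its own set.

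The genes that define the sort were present in every sample. Foxp3, the lineage transcription factor of Treg, had 541 ± 137 CPM in spleen, 517 ± 179 in thrombus and 403 ± 70.7 in vein wall (SD; n = 3, 4 and 3, as for all CPM below). Cd4 had 135 ± 19.7, 179 ± 118 and 94.2 ± 18.6 CPM, and Ptprc, which encodes CD45, had 1528 ± 523, 1248 ± 242 and 1239.8 ± 390.5 CPM. Il2ra, the high-affinity interleukin 2 receptor chain, had 208 ± 47.4, 325 ± 141 and 380.5 ± 22.4 CPM. Cd69 had 279.7 ± 58.5 CPM in spleen, 585 ± 174 in thrombus and 752 ± 120.3 in vein wall. Its log2 fold change against spleen was 1.07 ± 0.32 (SE) in thrombus and 1.43 ± 0.34 in vein wall, with adjusted p = 0.580 and 0.219 (edgeR), and 0.0248 and 0.00867 with the set of files as covariate. None of Foxp3, Cd4, Ptprc and Il2ra passed in any comparison. Foxp3 had log2 fold changes of -0.07 ± 0.34 and -0.43 ± 0.36 against spleen.

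Sparc (chromosome 11, 55394500 to 55423183, minus strand), a secreted matrix glycoprotein gene, was close to absent in spleen, with 3 reads over the 3 samples. It had 14 ± 17.4 CPM in thrombus and 11.7 ± 5.40 in vein wall. Pooled over samples this is 454 times the spleen level in thrombus (95% counting interval 155 to 2207) and 438 times in vein wall (149 to 2125). Against the spread between samples the change did not pass: the log2 fold change was 8.03 ± 1.73 in thrombus (adjusted p = 0.103) and 7.77 ± 1.73 in vein wall (adjusted p = 0.139, edgeR). Adjusted p was 0.0606 and 0.105 with the set of files as covariate, while in the fit first planned, of the 12 libraries separately, Sparc passed in both (adjusted p = 0.0149 and 0.0149), a fit that counts each near-duplicate as a sample of its own. The level ranged from 0.317 CPM in thrombus 3 to 39.5 in thrombus 4, while the vein wall samples had 6.01, 12.3 and 16.8 CPM.

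**Figure D2:**
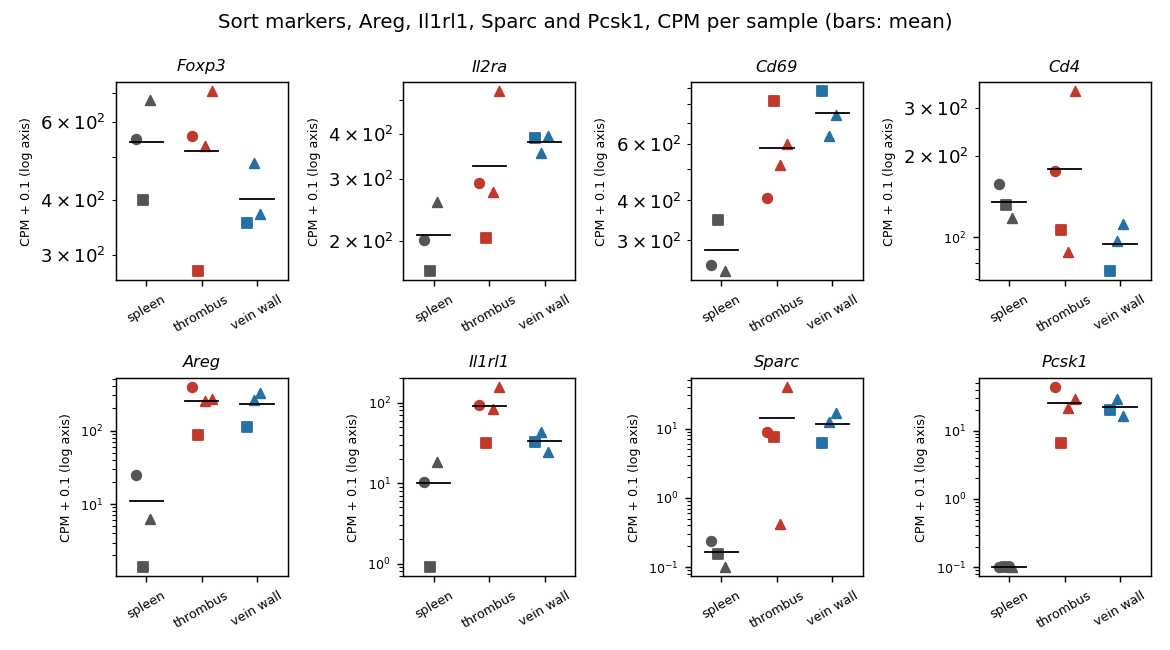
CPM (log axis, 0.1 added) of the sort markers Foxp3, Il2ra, Cd69 and Cd4 and of Areg, Il1rl1, Sparc and Pcsk1, 1 point per sample, with bars at the mean and shapes for the set of files. Foxp3 overlaps between the tissues, and Pcsk1 is at 0 in all 3 spleen samples and between 6.59 and 43.5 CPM in the others.

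The comparison of thrombus with spleen asks how Treg inside the clot differ from those of the lymphoid reference. In the thrombus samples 17 genes were higher and none lower (edgeR, 11722 genes tested). Try4 is among the 17, and RNA from pancreas may account for it, as described further below. The nuclear receptors Nr4a1 and Nr4a3, induced by TCR signals, had log2 fold changes of 2.49 ± 0.45 (SE; adjusted p = 0.0200) and 2.38 ± 0.46 (adjusted p = 0.0359). Crem, a cAMP-responsive transcription factor, rose from 85.7 ± 13 to 468 ± 109 CPM (log2 fold change 2.45 ± 0.41). The chemokine receptor Ccr2 rose from 10.8 ± 3.45 to 84.9 ± 32 CPM (2.97 ± 0.46), and Ccr7, a receptor for homing to lymphoid tissue, from 154 ± 29.8 to 797 ± 409.6 CPM (2.37 ± 0.39).

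Vps37b, an ESCRT-I subunit (chromosome 5, 124004641 to 124032270), rose from 19.4 ± 1.90 to 321 ± 186 CPM, a log2 fold change of 4.05 ± 0.48 (adjusted p = 0.000560). Coq10b, a coenzyme Q-binding protein gene (chromosome 1, 55052770 to 55072702), rose by 3.24 ± 0.40 on the log2 scale (adjusted p = 0.000729). Csrnp1 rose by 4.07 ± 0.56, the stress-responsive kinase Sgk1 by 2.90 ± 0.45, Spty2d1 by 2.88 ± 0.49, Ifrd1 by 2.62 ± 0.48 and the hypoxia-inducible lipid droplet gene Hilpda by 2.56 ± 0.36. The microtubule regulator Stmn1 rose from 61.9 ± 18.8 to 245 ± 64.8 CPM. Outside the naming rule, Tgif1 rose by 2.34 ± 0.31, and Gadd45b by 2.14 ± 0.38. Pcsk1, a prohormone convertase gene (chromosome 13, 75089826 to 75134861), had no read in spleen and 25.1 ± 15.4 CPM in thrombus, at least 851-fold higher against a floor of 3 reads over the spleen group. Try4, a pancreatic trypsinogen gene, had 1 spleen read and 25.3 ± 27.9 CPM in thrombus, a ratio of 2071 (counting interval 371 to 81866). All 17 genes were higher in every thrombus sample than in any spleen sample, and in each of the 3 sets of files. Over all tested genes, 4.97% had no overlap between the groups, where chance gives 5.71%.

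**Figure D3:**
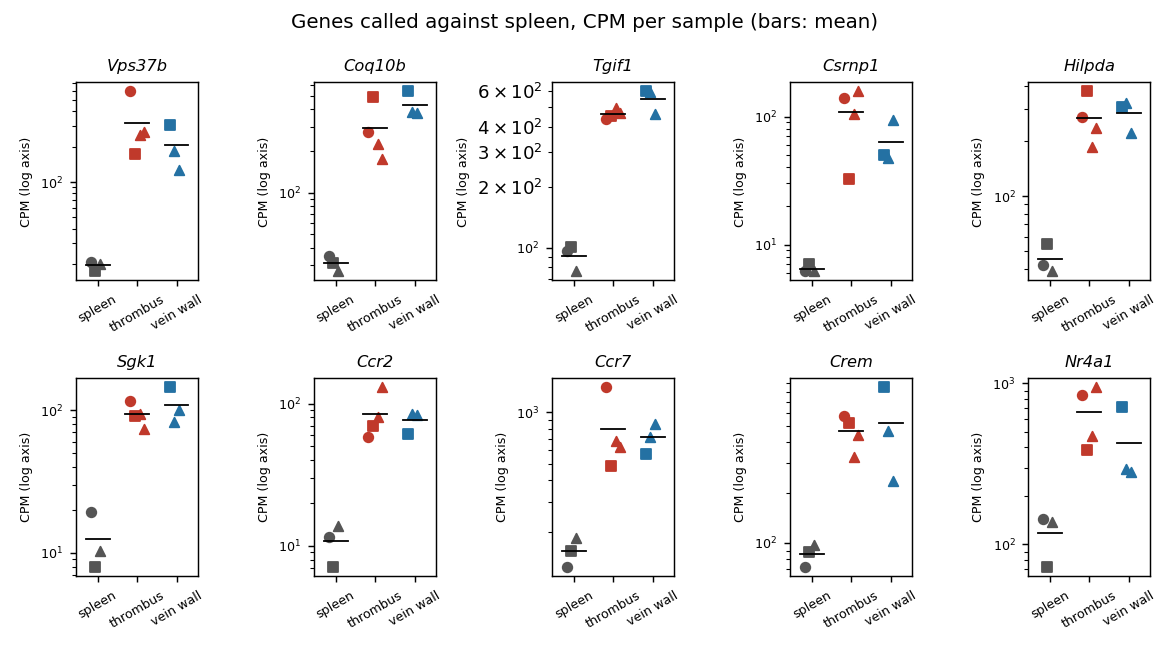
CPM (log axis) of 10 genes called in thrombus against spleen, 1 point per sample, with bars at the mean and shapes for the set of files. Every thrombus and vein wall sample lies above every spleen sample, as for Vps37b, with means of 19.4 CPM in spleen and 321 in thrombus.

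Of the 33 gene lists, 15 were higher in thrombus than in spleen and none lower. Without thrombus 2, 12 were higher and 2 lower. With an estimated correlation 3 of the 15 held: Th2 genes, chemokine receptors and fibroblast markers. With the set of files as covariate as well, 5 held: Th2 genes (adjusted p = 0.0335), TCR and immediate early genes (0.0335), proliferation (0.0335), lipid uptake (0.0457) and NF-kB (0.0479), while chemokine receptors (0.0530) and fibroblast markers (0.0546) did not. The Th2 list had 11 of 12 measured members above 0 and a median log2 fold change of 1.03 (adjusted p = 1.13e-07, or 0.0358 with an estimated correlation). No member was called over all genes, and 2 were called when adjusted over the list alone. Its members Gata3, Il1rl1, Ccr8, Il10, Areg and Pparg are also in the tissue and effector Treg list, so these lists are not separate evidence. Areg, an epidermal growth factor receptor ligand made by tissue Treg, had 10.9 ± 12.6 CPM in spleen and 249.6 ± 125 in thrombus, a log2 fold change of 4.53 ± 1.02 (adjusted p = 0.407, and 1.37e-06 with the set of files as covariate). Il1rl1, the interleukin 33 receptor, had 9.80 ± 8.72 and 91 ± 51 CPM, 3.21 ± 0.81 (adjusted p = 0.397, and 0.0301 with the covariate). The chemokine receptor list had 12 of 16 members above 0 and a median of 0.93 (adjusted p = 3.25e-06, or 0.0358 with an estimated correlation), with Ccr2 and Ccr7 called. Cxcr3, a receptor of Th1-type cells in the same list, had 332 ± 63 CPM in spleen and 182 ± 65 in thrombus (log2 fold change -0.87 ± 0.34, adjusted p = 0.987).

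In the fit without this covariate, the other main lists that passed did so at the preset correlation alone. TCR and immediate early genes had 22 of 27 members above 0, a median of 0.96, adjusted p = 1.10e-13, and adjusted p = 0.0791 with an estimated correlation. Adjusted over the list alone, 9 members were higher and 1 lower. Nfkbia, an NF-kB inhibitor, had 1343 ± 67.1 and 2616 ± 417 CPM (0.96 ± 0.28, adjusted p = 0.554, and 0.0163 with the set of files as covariate). Proliferation genes had 26 of 27 above 0 and a median of 1.72 (adjusted p = 5.91e-13, and adjusted p = 0.111 with an estimated correlation), with Stmn1 called. Tissue and effector Treg genes had 22 of 29 above 0 and a median of 0.72 (adjusted p = 4.57e-06, estimated correlation adjusted p = 0.0844). Tissue residence genes, with Crem called, had a median of 0.68 (adjusted p = 0.000429, estimated correlation adjusted p = 0.111). Naive and lymphoid recirculation genes, in which Ccr7 was the 1 called member, had a median of 0.49 (adjusted p = 0.000614, estimated correlation adjusted p = 0.0808).

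Lipid uptake and synthesis genes had 22 of 24 members above 0 (median 0.85, adjusted p = 1.45e-06, estimated correlation adjusted p = 0.140). Their member Dgat2, a triglyceride synthesis enzyme, had 10.7 ± 7.05 and 50.4 ± 34.1 CPM (2.24 ± 0.79, adjusted p = 0.846). The NF-kB and TNF list had a median of 0.30 (adjusted p = 0.000429, estimated correlation adjusted p = 0.129), and Rel, an NF-kB subunit, had 70.8 ± 43.9 and 241 ± 29.2 CPM (1.77 ± 0.41, adjusted p = 0.172, and 0.00303 with the set of files as covariate). The hypoxia list, with Hilpda called, had a median of 0.10 (adjusted p = 0.00475, estimated correlation adjusted p = 0.147). The Th17 list had a median of 0.86 (adjusted p = 0.0174, estimated correlation adjusted p = 0.136), and its member Tmem176a had 3.58 ± 0.753 and 30 ± 12.8 CPM (3.07 ± 0.95, adjusted p = 0.592).

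Lists that did not pass in thrombus against spleen were Treg identity (12 of 18 members above 0, adjusted p = 0.330), suppressive mediators (0.0518), extracellular matrix (0.164), coagulation (0.493), heat shock (0.213), Th1 genes (0.997), follicular genes (0.997), interferon response (0.213), glycolysis (0.139), oxidative phosphorylation (0.745) and heme and iron (0.285). The heat shock list was higher in thrombus with the set of files as covariate at the preset correlation (adjusted p = 0.0148, and 0.137 with an estimated correlation). Among their members, Ctla4, an inhibitory receptor of Treg, had 651 ± 127 and 1041 ± 271 CPM (0.68 ± 0.31, adjusted p = 1.000). The coinhibitory receptor Havcr2 had 0.394 ± 0.468 and 9.38 ± 8.38 CPM (4.58 ± 1.60, adjusted p = 0.821). Plaur, the urokinase receptor, had 0.928 ± 1.11 CPM in spleen and 15.3, 125, 14.7 and 15 in the thrombus samples (log2 fold change 5.57 ± 1.38, adjusted p = 0.465).

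Markers of other cell types moved with tissue too. The fibroblast list was higher in thrombus (8 of 9 measured members above 0, adjusted p = 2.52e-08, or 0.0358 with an estimated correlation), with Dcn, a matrix proteoglycan, at 4.08 ± 3.38 CPM in thrombus and 2 reads in spleen. Dendritic cell (adjusted p = 0.00303), platelet (0.00625) and B and plasma cell markers (0.00439) were higher at the preset correlation alone (adjusted p = 0.307, 0.136 and 0.377 with an estimated correlation). Among the thrombus samples, thrombus 2 held the most of each of these 4 lists: its summed dendritic cell markers reached 12606 CPM against a spleen mean of 2104, and its macrophage markers 4435 against 1061. Adjusted p was 0.941 for macrophages and monocytes, 0.178 for neutrophils, 0.493 for erythroid cells, 0.556 for CD8 T and NK cells, 0.347 for mast cells, basophils and ILC2, 0.241 for endothelial cells and 0.386 for smooth muscle cells. Klrb1c, a natural killer receptor, had 24.3 ± 13.6 CPM in spleen and 2.04 ± 2.38 in thrombus (-3.55 ± 1.13, adjusted p = 0.636). Outside the join, the immunoglobulin constant gene Ighm went against the B and plasma cell list. It had 1724, 1520 and 1424 CPM of gene reads in thrombus 1, 3 and 4. Spleen 1, 3 and 4 had 2073, 1908 and 1973.5, and set 2 held no Ighm read. Jchain and Igkc, also outside the join, went with the list in set 1. They had 153 and 24.7 CPM in thrombus 1 and 63.3 and 8.45 in spleen 1.

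At an unadjusted p under 0.05 there were 485 genes, where 586 would pass by chance. With the set of files as covariate, which lowers the spread, 50 genes were higher and 3 lower, among them all 17. Without spleen 2 the calls fell to 6, without the spleen 3-4 pair to 8, and without spleen 1 they rose to 34.

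The comparison of vein wall with spleen covers Treg of the vessel wall around the clot. Here 13 genes were higher and none lower, and all 13 were among the 17 called in thrombus. They include Try4, which RNA from pancreas may account for here too. Coq10b rose from 31 ± 3.95 to 432 ± 92.9 CPM (log2 fold change 3.80 ± 0.42, adjusted p = 0.000429). Vps37b rose by 3.41 ± 0.48 on the log2 scale (adjusted p = 0.00244), the transcriptional repressor gene Tgif1 by 2.59 ± 0.32 (adjusted p = 0.000668) and Hilpda by 2.64 ± 0.37 (adjusted p = 0.00244). Ccr2 reached 76.3 ± 12.9 CPM (2.81 ± 0.47, adjusted p = 0.0136) and Ccr7 713 ± 144 CPM (2.21 ± 0.40, adjusted p = 0.0251).

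Sgk1 rose by 3.13 ± 0.46, Crem by 2.60 ± 0.43, Csrnp1 by 3.30 ± 0.56, Ifrd1 by 2.68 ± 0.49 and, outside the naming rule, Gadd45b by 2.17 ± 0.40. Pcsk1 had 21.9 ± 6.52 CPM, at least 669-fold above the floor of 3 reads over the spleen group, and Try4 had 13.9 ± 9.41 CPM, 1533 times its spleen level (counting interval 275 to 60593). Every vein wall sample exceeded every spleen sample for these 13 genes, in both sets of files that hold the tissues. Over all tested genes 13.2% had no overlap, where chance gives 10%. Nr4a3 had 147 ± 49 CPM (2.36 ± 0.47, adjusted p = 0.0638, and 0.000435 with the set of files as covariate), and the antiproliferative gene Btg2 had 430.4 ± 45.7 CPM against 156 ± 13.1 in spleen (1.46 ± 0.33, adjusted p = 0.138, and 0.0163 with the covariate). Stmn1 had 182 ± 43.4 CPM (1.56 ± 0.38, adjusted p = 0.219, and 0.0292 with the covariate).

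In vein wall 13 lists were higher than in spleen and 1, erythroid markers, was lower. Without vein wall 1, 12 were higher and 4 lower, and without spleen 2, 9 were higher and 1 lower. With an estimated correlation the fibroblast list alone held (adjusted p = 2.23e-06, or 0.0362 with an estimated correlation). With the set of files as covariate as well it did not (0.0546), and TCR and immediate early genes (0.0457), Th2 genes (0.0479) and proliferation (0.0479) passed. Dcn was at 7.59, 49.5 and 0.274 CPM in the vein wall samples. TCR and immediate early genes had 19 of 27 members above 0 and a median of 0.72 (adjusted p = 1.14e-07, estimated correlation adjusted p = 0.135). The Th2 list had a median of 1.01 (adjusted p = 0.000272, estimated correlation adjusted p = 0.0844). In it Areg had 229 ± 107 CPM (4.41 ± 1.03, adjusted p = 0.411, and 1.45e-06 with the set of files as covariate), and Il10, an anti-inflammatory cytokine, had 93.5 ± 50 CPM against 27.1 ± 25.9 (1.79 ± 0.69, adjusted p = 0.805). Tissue and effector Treg genes had a median of 0.58 (adjusted p = 0.000429, estimated correlation adjusted p = 0.135), with Id2, a transcriptional regulator, at 901 ± 316 CPM (1.24 ± 0.42, adjusted p = 0.693). Tissue residence genes had a median of 0.56 (adjusted p = 0.00117, estimated correlation adjusted p = 0.135). Within the sets their median log2 difference was -0.218 in set 2 and 0.800 in set 3.

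Chemokine receptors had 8 members above 0 and 8 below (median 0.07, adjusted p = 0.00625, estimated correlation adjusted p = 0.111), Ccr2 and Ccr7 being called and Cxcr3 at -1.12 ± 0.37 (adjusted p = 0.647). Naive and recirculation genes (0.0211), hypoxia (0.0191), proliferation (0.00124), oxidative phosphorylation (0.00407) and lipid uptake (0.00124) were higher at the adjusted p given, and with an estimated correlation their adjusted p was 0.140, 0.207, 0.377, 0.414 and 0.307. Cox6c, a subunit of cytochrome c oxidase, had 856 ± 219.6 CPM (0.69 ± 0.38, adjusted p = 0.929), Pclaf, a replication factor, 20.5 ± 11 (3.29 ± 1.11, adjusted p = 0.693) and the fatty acid-binding protein gene Fabp4 11.3 ± 2.62 (4.25 ± 1.54, adjusted p = 0.766). Dendritic (0.0170) and B and plasma cell markers (3.25e-06) were higher, and erythroid markers lower (0.00158), with adjusted p of 0.377, 0.180 and 0.309 under an estimated correlation. Ms4a1, a B cell marker, had 147 CPM in vein wall 1 and 17 and 15.4 in the others. Ighm, an immunoglobulin constant gene outside the join, went the other way in set 3. It had 1110, 929 and 914 CPM of gene reads in vein wall 2, 3 and 4. Spleen 3 and 4 had 1908 and 1973.5, and set 2 held no Ighm read. Jchain, also outside the join, was uneven. It had 46.1 CPM in vein wall 2 and 0 in spleen 3 and 4, but 0 in vein wall 1 and 26.7 in spleen 2. The list result therefore covers the joined genes only. Summed dendritic cell markers were 13302 CPM in vein wall 1 and 2955 and 3067 in the others, against 1534, 1931 and 2845 in the spleen samples.

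The lists that did not pass in vein wall, with their adjusted p, were Treg identity (0.252), extracellular matrix (0.953), coagulation (0.176), heat shock (0.556), suppressive mediators (0.252), Th1 (0.493), Th17 (0.268), follicular (0.456), interferon (0.767), NF-kB (0.124), glycolysis (0.169), heme and iron (0.863), macrophages (0.0775), neutrophils (0.720), platelets (0.719), CD8 T and NK cells (0.493), mast cells, basophils and ILC2 (0.124), endothelial cells (0.862) and smooth muscle cells (0.932). The heat shock list was higher with the set of files as covariate at the preset correlation (adjusted p = 0.0301, and 0.160 with an estimated correlation). Hmox1, which degrades heme, had 36.2 ± 11.3 CPM in spleen and 6.26 ± 2.20 in vein wall (-2.53 ± 0.90, adjusted p = 0.757). The iron exporter Slc40a1 had 8.56 ± 7.45 CPM in spleen and 0.0262 ± 0.0269 in vein wall (-8.07 ± 2.53, adjusted p = 0.558). In vein wall 639 genes had an unadjusted p under 0.05, where 586 would by chance. With the set of files as covariate 45 genes were higher and 3 lower, and the calls fell to 5 without spleen 2 and to 6 without spleen 3-4.

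**Figure D4:**
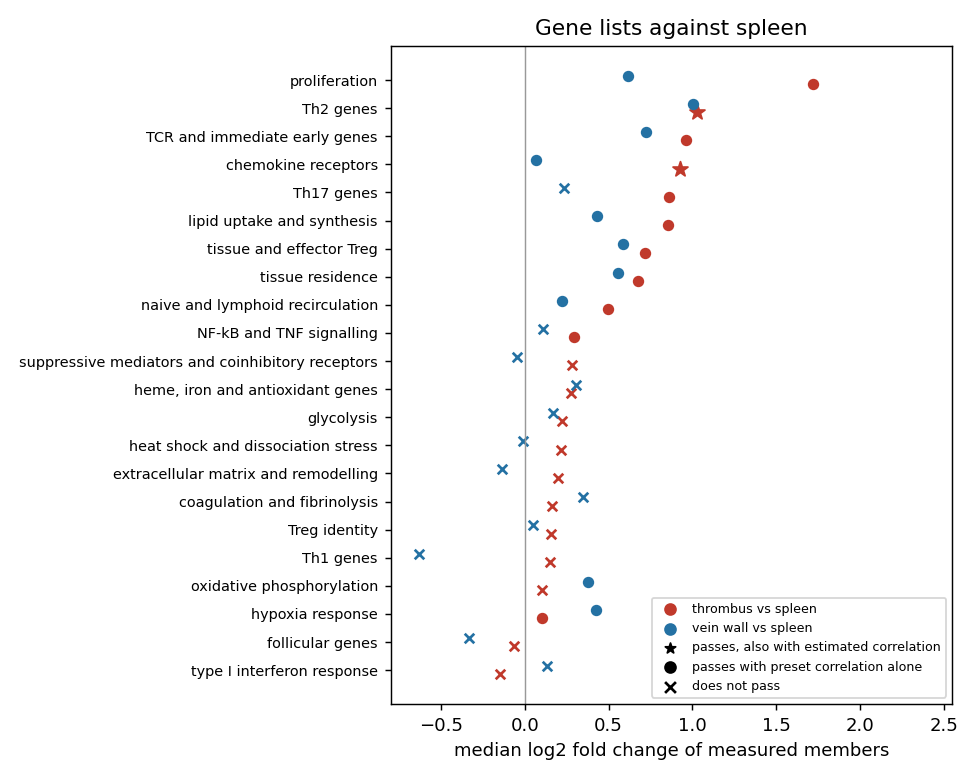
Median log2 fold change of the measured members of 22 gene lists, thrombus against spleen in red and vein wall against spleen in blue. Stars mark lists that passed with both the preset and the estimated correlation, circles those that passed with the preset correlation alone and crosses those that did not pass; Th2 genes had medians of 1.03 and 1.01.

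Thrombus and vein wall Treg were then compared directly. No gene was called by edgeR, with 342 genes at an unadjusted p under 0.05 against 586 by chance. DESeq2 called 10, edgeR with no filter on low counts 2, and limma-voom 0. The interleukin 33 receptor gene Il1rl1 had 91 ± 51 CPM in thrombus and 33.4 ± 9.29 in vein wall (1.45 ± 0.75, adjusted p = 1.000). The mitotic genes Ube2c and Aurka had log2 fold changes of 4.98 ± 1.52 and 2.45 ± 0.95, and Jun of 1.43 ± 0.68 (adjusted p = 1.000, 1.000 and 1.000).

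Between thrombus and vein wall 6 lists passed at the preset correlation and none with an estimated one. Proliferation genes were higher in thrombus (22 of 27 members above 0, median 0.69, adjusted p = 0.000921, estimated correlation adjusted p = 0.377). Oxidative phosphorylation genes were lower in thrombus (24 of 26 below 0, median -0.27, adjusted p = 0.00124, estimated correlation adjusted p = 0.377), with Cox5a at -0.65 ± 0.36 and Ndufb5 at -0.59 ± 0.33. Markers of macrophages (0.0137), platelets (0.0293) and erythroid cells (0.00458) were higher in thrombus at the adjusted p given, and those of B and plasma cells (0.00439), with Fcmr at -1.33 ± 0.59, were lower. Ighm, outside the join, went against the B and plasma cell list in set 3. It had 1520 and 1424 CPM of gene reads in thrombus 3 and 4. Vein wall 2, 3 and 4 had 1110, 929 and 914. Summed erythroid markers were uneven, at 7.14, 2040, 10.1 and 1554 CPM in the thrombus samples and 2.47, 3.97 and 50.8 in the vein wall samples. The macrophage list did not pass and turned its direction without thrombus 2. With the set of files as covariate at the preset correlation, proliferation (adjusted p = 0.0801) and platelets (0.114) did not pass and the other 4 did. Without thrombus 1 or without thrombus 2 the lists that passed fell from 6 to 3 (2 higher and 1 lower, and 1 higher and 2 lower), and without thrombus 3 there were 8. With an estimated correlation the 4 lists of other cell types had adjusted p of 0.570, 0.201, 0.365 and 0.377. The other 27 lists had adjusted p from 0.0575 (neutrophils) to 0.960 (hypoxia), with Treg identity at 0.719 and TCR and immediate early genes at 0.213.

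The changes in thrombus and vein wall were measured against the same spleen samples, so part of their likeness comes from those samples. All 13 genes called in vein wall, Try4 included, were called in thrombus, in the same direction. The genes called in thrombus alone were Nr4a1, Nr4a3, Spty2d1 and Stmn1, and none of them differed between thrombus and vein wall by the direct test. Nr4a3 (adjusted p = 0.000435), Spty2d1 (0.00379) and Stmn1 (0.0292) were called in vein wall too with the set of files as covariate, and Nr4a1 (0.194) was not. Simulated unchanged groups against the same spleen samples shared 0.075 higher calls on average over 40 data sets, and at most 1. They called only 0.225 genes in thrombus and 0.5 in vein wall on average. A small overlap was thus fixed in advance and does not test the 13 shared calls. Independent lists of the real sizes would share 0.0189. Over 6363 genes with a mean of at least 20 CPM, the covariance of the fold changes was 0.299, against a simulated mean of 0.212 (0.182 to 0.255), a difference of 0.0865. The simulation covers the shared spleen samples and not the shared sets of files. Deviations from the tissue mean were correlated between libraries of different tissues, with near-duplicates counted separately. Their median correlation was 0.123 over 20 pairs of 1 set and -0.0750 over 28 pairs of different sets. Deviations from a mean sum to 0, which pushes some pairs below 0. The covariance difference is therefore not free of the sets. The correlation of the fold changes across genes, which are not independent replicates, was 0.714 against 0.534, and 70.1% had the same sign against 68.0%. With the 4 spleen libraries taken separately and split 2 and 2 between the comparisons, 1 gene was shared in each of the 6 assignments, where the shorter list held 1 or 2 genes, so that no more than 2 could be shared. In 4 of the 6, spleen 3 and spleen 4 stood on opposite sides.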

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

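The tests of acinar RNA, of the file sets, of tissue dissociation and of other splits, and the sum of acinar genes without Cela1, were chosen only after the result was seen; for fibroblasts, endothelial cells and platelets the bounds were written before the values they measure, and the demand that a bound be met beyond its spread was added afterwards.

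Among 70 values tested over the 4 thrombus samples (genes printed in the text and library measures), 3 had 1 sample far from the rest, where chance gives about 5%. Plaur stood apart in thrombus 2 (gap over range 0.981), at 125 CPM against 14.7 to 15.3 in the others. Slc40a1 stood apart in thrombus 1 (0.939), at 1.43 CPM. The mitochondrial share of exon reads was low in thrombus 2 (0.929), at 0.231% against 2.90% to 3.10%. The other libraries of set 2, spleen 2 and vein wall 1, had 0.410% and 0.257%.

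The changes against spleen of 6 lists differed between thrombus and vein wall by the direct camera test. They were proliferation (adjusted p = 0.000921), oxidative phosphorylation (0.00124), macrophages and monocytes (0.0137), platelets (0.0293), erythroid cells (0.00458) and B and plasma cells (0.00439). None held with an estimated correlation, and with the set of files as covariate proliferation (0.0801) and platelets (0.114) did not pass. The macrophage list had an adjusted p of 0.847, with its direction turned, without thrombus 2, and 0.546 without vein wall 3-4.

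Outside the joined genes, Xist had 53.6 CPM of gene reads in vein wall 1, above the highest spleen library, spleen 2 at 22.8. Set 2 libraries held both Xist and the Y-linked gene Ddx3y, at 58.9 to 97.2 CPM, set 1 held Xist with Ddx3y at 0.306 and 0.353, and the libraries of set 3 held Ddx3y with no Xist read.

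Digestive enzyme transcripts of the exocrine pancreas were present in thrombus and vein wall libraries. Of 11 acinar genes not looked at before and with at most 0.678 CPM in spleen, 9 (81.8%) were detected in thrombus or vein wall with a mean above the highest spleen sample, against 1481 of 9811 other genes as low in spleen (15.1%; Fisher p = 1.71e-06, which takes genes as independent), as RNA of acinar cells requires; the test first written, a share of detected genes alone, could hardly fail, since 6 of the 9 had no spleen read. Leaving out the 1 gene that spleen also expressed, Cela1, the sum of the 24 acinar genes listed was 2.20 to 7.15 CPM in spleen, 7.20 in thrombus 1, 44.2 and 37.4 in the set 2 samples thrombus 2 and vein wall 1, and 258 to 666 in the 4 samples of set 3. The spleen sample of set 3 held 0.00853 of the lowest tissue sample of that set (0.0797 with Cela1). Only 12 of the 24 genes had not been looked at before, so this ratio was partly fixed by the choice of genes. Among those 12, Cpa1, Ctrl and Try5 had 0.0776, 0.104 and 0.0129 CPM in that spleen sample. They had 1.02 CPM or more in every tissue sample of set 3, while others of the 12 were absent from some. For these 3 genes this argues against a difference between file sets alone. RNA from pancreas, which a CD45+ CD4+ gate would remove as cells, may account for Try4, Clps and Amy2a1, and whether it entered with the tissue or in a later step stays open.

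Sparc reads in thrombus and vein wall were set against 3 other sources, all of which the CD45+ CD4+ gate would remove as cells. The platelet transcripts Pf4 and Ppbp summed lay below Sparc in 5 of the 6 samples with over 3 CPM of Sparc, counting error included. Thrombus 2, at 49.4 against 7.37 CPM, is the exception. This argues against platelets as the source in the 5 samples. Cdh5, Egfl7, Cldn5 and Esam summed lay below 0.5 of Sparc in 4 of 6, counting error included and exactly the number the bound asked for. For these 4 markers alone, this argues against endothelial cells in those samples. Pecam1, also named as a marker beforehand, is not in that sum. The whole endothelial list summed above Sparc in all 7 samples (45.7 to 77.2 CPM), and to 36.7 to 57.4 CPM in spleen. Endothelial RNA is therefore not excluded beyond the 4 markers. Fibroblast RNA stays open: over the 7 samples Spearman's rho with the summed fibroblast list, of which 1 of 15 genes exceeds 5 CPM in spleen, was 0 (exact permutation p = 1, 95% interval -0.753 to 0.753), while the bound written beforehand, rho below 0.2, is met by the value itself and spanned by its interval; the list lay below Sparc in 1 of 6 samples (thrombus 4, 22.7 against 39.5 CPM), where fibroblasts as the only source allow none and the bound against them asks for 2; Pearson's r was -0.114 (exact permutation p = 0.781) and r without the 2 farthest samples was 0.0125, with too few samples per set for values within sets. Col1a1, Col1a2 and Col3a1 summed lay below Sparc in all 6, a comparison made after the values were seen. The biological explanation, Sparc expressed by tissue Treg, may hold as well and was not tested.

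The list of immediate early genes was higher in thrombus and vein wall than in spleen at the preset correlation (adjusted p = 1.10e-13 and 1.14e-07, or 0.0791 and 0.135 with an estimated correlation), with 22 and 19 of 27 members above 0 and 2 and 0 called over all genes. A difference between file sets is excluded as the whole cause, because with the set as covariate and an estimated correlation the list had adjusted p of 0.0335 and 0.0457, and its median log2 difference within sets was above 0 in each (0.72, 1.29 and 1.33 in thrombus, 1.46 and 0.98 in vein wall). Stress of tissue dissociation cannot be told apart from a response to the tissue. The heat shock list was higher in both tissues with the set as covariate at the preset correlation (camera, adjusted p = 0.0148 and 0.0301). In thrombus its adjusted p was 0.137 at an estimated correlation, and its median log2 fold change was 0.20 over 14 genes. The 95% interval of that median, 0.11 to 0.52, comes from resampling the 14 genes and leaves out the spread between samples. How the cells were released from each tissue is not given in the sources used here. TCR signals in the tissue may also raise these genes, and this was not tested.

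Other splits of the samples were counted for each comparison. For thrombus against spleen, 1 of 35 splits, the real one, gave 17 genes or more, and the highest other gave 2. That share takes samples as exchangeable between file sets, while the first principal component followed the set (r2 = 0.902). Of these splits 12 keep the number of thrombus samples in each set, where the highest other gave 1. These are too few for a share under 0.05, so chance is not excluded. With the set as covariate, 1 of 35 gave 53 or more, but a split of spleen 3-4 with thrombus 2, 3 and 4 against the rest gave 51. In that split set 2 alone holds both sides, so its contrast rests mostly on thrombus 2 against spleen 2. Whether its 51 genes are those of the real split was not compared. How far the 53 calls depend on set 2 therefore stays open. Among the 12 splits that keep the number of thrombus samples in each set, the highest other gave 4 in this fit. These splits are again too few for a share under 0.05. For vein wall against spleen the real split gave 13 and the highest other 0, 1 of 10, too few splits for a share under 0.05; with the set as covariate it gave 48 and the highest other 1. For thrombus against vein wall all 35 splits gave at least the real count of 0, and the split that follows set 3 (thrombus 3, thrombus 4, vein wall 2 and vein wall 3-4 against the rest) gave 17, while the fit with set as covariate gave 0.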

How the results depend on the processing

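Unique exon reads, gene reads with introns, the exon length filter, omission of a summed pair and the 12 libraries with the set as covariate were chosen after the data were seen. The 12 libraries separately and the split of the spleen libraries were part of the first plan. The cause of the changes below was not tested. Calls in thrombus against spleen and vein wall against spleen, and the genes shared, main values 17, 13 and 13, were 80, 66 and 52 with no filter on low counts, 53, 48 and 40 with the set of files as covariate, 105, 119 and 63 with DESeq2, 33, 24 and 20 with limma-voom, 9, 8 and 8 with RPKM and a pseudocount of 1 (7 shared with 0.1), 35, 51 and 29 with 12 libraries separately, and 111, 210 and 99 with those and the set as covariate. DESeq2 gave 30 lower among its 119. Unique exon reads gave 13, 7 and 7, gene reads with introns 9, 10 and 9, exon lengths within 10% 11, 10 and 9 (2972 genes tested), and only the 2 tissues compared 13, 17 and 11. Of the 17 and 13, limma-voom kept 16 and 11, RPKM with a pseudocount of 1 kept 6 and 6, gene reads 8 and 9, and exon lengths within 10% 8 and 6, while DESeq2, the covariate and the 12 libraries kept all. The direct comparison gave 2 with no filter and 10 with DESeq2. With spleen libraries split 2 and 2, 1 gene was shared in each assignment, where the shorter list held 1 or 2, which caps the overlap.

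Leaving out replicates gave 6 to 34 calls in thrombus, 5 to 28 in vein wall, 5 to 27 shared and 29 to 39 gene lists, the lowest calls without spleen 2 and the highest without spleen 1. Without spleen 3-4 the values were 8, 6 and 6. Every setting kept 0 calls in the direct comparison except the 2 named. All 17 and 13 calls were kept under RLE and the stricter filter. Gene lists passing fell from 35 to 4 with an estimated correlation and to 4 with fry. In the direct comparison they fell from 6 to 4 with the set as covariate and to 3 without thrombus 1, without thrombus 2 or with the replicate block, and were 8 without thrombus 3. Sparc passed with 12 libraries separately in thrombus and vein wall (0.0149 and 0.0149), not in the main fit.

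The replicate number as a block on the 12 libraries gave 52, 65 and 43, and 32 lists. Ddx3y, a Y-linked gene, had 0.306 and 0.353 CPM of gene reads in spleen 1 and thrombus 1 but 58.9 in vein wall 1. Xist had 22.8 and 19.8 in spleen 2 and thrombus 2 but 0 in vein wall 2. These values argue against vein wall 1 and vein wall 2 coming from the same mice as the spleen and thrombus samples of their number. The block treats these samples as matched. Whether the numbers pair spleen with thrombus, or the other vein wall samples with either, stays open. Spleen and thrombus of the same number had correlations of 0.401, 0.265, 0.156 and 0.0913, each within 1 set of files, where number and set are hard to part: in set 3 the crossed pairs had 0.141 and 0.106. Over all tissues same-number correlations ran from -0.0715 to 0.401, and libraries of 1 set were closer (median 0.123) than those of others (-0.0750). All these correlations are of deviations from the tissue mean, between the 12 libraries with near-duplicates counted separately.

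Of 207 gene and comparison pairs named by the rule, 25 turned sign under some alternative, none of them called. Among values printed here, Cd4 in thrombus against spleen ran from -0.13 to 0.63 and Foxp3 from -0.25 to 0.16 over omitted replicates, and Ptprc in vein wall was 0.0428 with 12 libraries and set. Foxp3 between thrombus and vein wall was -0.11 with unique exon reads. Sparc there was -1.46 with limma-voom, -0.27 and -0.79 with RPKM, -0.75 with the replicate block and -1.09 to 0.66 over omitted replicates. The list of macrophages and monocytes, thrombus vs vein wall, had an adjusted p from 0.000211 (without thrombus 4) to 0.847 over omitted replicates, the latter without thrombus 2 and with its direction turned, and 0.546 without vein wall 3-4. Depth limits genes below a few CPM, and in simulation no 2-fold change was recovered.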

Other observations

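The genes named here were chosen after their values were seen, from the fit with the set of files as covariate (edgeR). They form no tested group. Junb, an AP-1 subunit, had 531 ± 512 CPM in spleen, 1919.9 ± 857 in thrombus and 1362 ± 103 in vein wall, with adjusted p = 0.000157 and 0.000435, against 0.592 and 0.870 without the covariate. Fosl2, another AP-1 subunit, had 7.11 ± 10.5, 107 ± 47.5 and 73.2 ± 28.2 CPM (adjusted p = 0.000181 and 0.000435, against 0.636 and 0.766). Ppp1r15a, of the integrated stress response, and the cell cycle inhibitor Cdkn1a were also higher in both, at 59 ± 49.9 and 31.1 ± 32.6 CPM for Cdkn1a against 7.69 ± 6.13 in spleen. The phosphatase genes Dusp10 and Dusp14, the transcription factor Bhlhe40, the small protein Crip1 and the cofactor Hopx were higher in both tissues as well.

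Fewer genes were lower in the same fit. In thrombus they were Epcam (88.4 ± 39.5 CPM in spleen, 20.7 ± 19.7 in thrombus), Spint2 (276 ± 21.4 and 133 ± 41.1) and the GTPase of immunity-associated protein gene Gimap7 (701 ± 626 and 312 ± 281). In vein wall they were Zfp3, Asb2 (60.7 ± 9.47 CPM in spleen, 8.29 ± 4.04 in vein wall) and Susd2. Tnfsf4, the ligand of OX40, had 1 spleen read, 8.28 ± 7.96 CPM in thrombus and 14.2 ± 16.3 in vein wall. Il5, a type 2 cytokine gene with no spleen read, had 0.908, 93.9, 3.17 and 0 CPM in the thrombus samples and 22.2, 7.51 and 0.0250 in the vein wall samples, highest in set 2 in both tissues.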
